A study of Mus musculus with 16 samples.

How the data were processed

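RNA sequencing was done on G1E-ER4 cells, a mouse erythroid line that lacks its own GATA1 protein and carries GATA1 fused to the ligand-binding part of the estrogen receptor. Beta-estradiol moves the fusion protein into the nucleus. Per the labels, cells were given 0, 12.5, 25, 50, 75, 100, 150 or 200 nM beta-estradiol, with 2 replicates at each of the 8 doses and 16 libraries in all. The cells grew in Iscove's medium with serum, stem cell factor and erythropoietin. They were lysed in Qiagen RLT buffer and prepared with Smart-seq2, which copies polyadenylated transcripts along their length, does not keep the strand and uses no molecular identifiers. The length of the exposure to beta-estradiol is not given in the sources used here.

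The authors deposited raw read counts per gene symbol for all 16 libraries in a single table of 23410 symbols. Per the submitters' processing notes, bcl2fastq, STAR and the mm10 build were used. The versions, the counting program, the annotation and the handling of reads with several matches are not given in the sources used here. The values were whole numbers with a different total in each library, so they were taken as counts that had not been normalised. Totals ran from 9393156 counts (150 nM, replicate 2) to 15802510 counts (12.5 nM, replicate 2). This processing bears on the values. Reads of near-identical genes such as the alpha-globin pair Hba-a1 and Hba-a2 can be split or dropped by the counter, so single members are uncertain. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart. Amplified reads are not independent molecules, so counting intervals cover counting error alone.

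Differential expression was computed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the dose as the group, which left 10080 genes. Libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion was fitted to all 16 libraries with the dose as a factor, so that all doses shared an estimate of the spread. P-values were adjusted by Benjamini-Hochberg within each contrast, and genes under 0.05 were called. Each dose was compared with 0 nM, each dose with its neighbour and each lower dose with 200 nM. An F test covered all doses together, and a slope on log2(dose/12.5 + 1) gave a dose trend. A gene peaked or dipped at an intermediate dose where it was higher, or lower, than at both 0 and 200 nM, with the larger of the 2 p-values adjusted per dose. Expression is given as TMM-scaled CPM, mean ± SD with n = 2. Log2 fold changes are given ± their size divided by the square root of the F statistic of the test, called the standard error here. For large changes from few counts at 0 nM this error can be too small. That of Hbb-bh1 at 200 nM was 0.09, while leaving out each library of the 2 doses in turn gave 11.33 to 12.27.

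The half-maximal dose was read per gene for genes called and changed at least 2-fold at 200 nM. Mean log2 CPM with a prior count of 2 was made monotone over the doses, and the point halfway between 0 and 200 nM was found by linear interpolation. Its spread came from all series that take 1 of the 2 libraries at each dose. Gene lists numbered 30, with 568 entries of which 543 matched a symbol in the table, 8 of them under an older symbol. Each list was described by its members higher, lower and not called, and tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes. The same test with an estimated correlation was run beside it, and p-values were adjusted over 189 tests of lists at the 7 doses.

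Named genes followed a rule. At 200 nM against 0 nM these were the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 20 CPM at the dose with the higher mean and the same direction in each pairing of a 200 nM with a 0 nM library. For every other contrast, peak or dip the 3 highest and 3 lowest were taken. Unnamed gene models, pseudogenes and mitochondrial genes were counted but not named. Gata1, Gata2 and 2 to 4 members of each list, by smallest adjusted p at 200 nM, were added. Of the genes picked by this rule 3 are not reported here. The groups, tests, lists, naming rule and main alternative settings were fixed before the data were examined. Gene positions came from GENCODE release M21 on GRCm38, where 23008 of the symbols had a single place.

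The test was tried on simulated counts for 200 nM against 0 nM, with known changes in 200 genes. It called 52% of the genes changed 1.25-fold, 75.5% of those changed 1.5-fold, 85.7% of those changed 2-fold and 100% of those changed 4-fold, with 11 false calls among 9716 unchanged genes. Only those 200 genes changed, as many up as down, whereas in the data 80.0% of the genes tested were called at 200 nM. The simulation therefore did not test the scaling of libraries. The pass mark for 2-fold genes was lowered after the first simulation. In simulated data without change 0 of 27 lists were called. Genes were drawn independently there, so this did not test lists whose genes vary together. True half-maximal doses of 40, 60, 90 and 120 nM came back as medians of 46.1, 66.1, 90.6 and 113.8 nM over 50 genes each.

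The alternatives were DESeq2 size factors or library size in place of TMM, no filter on low counts, a filter of at least 10 CPM in at least 2 libraries, DESeq2 1.42.0 and limma-voom in place of edgeR, the 4 libraries of each contrast alone, a 2-fold minimum, other dose scales, a replicate block, each library left out in turn, and other readings of the half-maximal dose. Replicates of each dose were compared before they were averaged. Chi-square per degree of freedom lay between 1.65 and 3.71 over the 8 doses, more than counting noise gives, so no pair looked like 2 copies of the same library. The labels list the 2 as separate samples, and each dose counted as 2 samples on that ground. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.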

Results

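Expression of 23410 gene symbols was counted in 16 libraries of G1E-ER4 cells at 8 doses of beta-estradiol from 0 to 200 nM, with n = 2 at each dose. The series was made to move GATA1, the master regulator of erythroid genes, into the nucleus by steps and to turn on its target genes. Library totals ran from 9393156 to 15802510 counts. The first principal component held 82.3% of the variance and ordered the libraries by dose from 25 nM upward, and the second held 5.88%. The share of counts in globin genes went from 0.151% ± 0.0002 at 0 nM to 5.85% ± 0.05 at 200 nM (SD, n = 2). The share in Rn45s, the ribosomal RNA precursor, went from 9.57% ± 0.06 to 15.0% ± 0.5. TMM factors averaged 1.10 at 0 nM and 0.844 at 200 nM.

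Gata1 transcripts stood at 711 ± 62 CPM at 0 nM and rose to 1643 ± 46 CPM at 200 nM (SD, n = 2), a log2 fold change of 1.21 ± 0.07 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.28e-07). Gata1 lies on chromosome X, 7959260 to 7978071 on the minus strand (GRCm38). Its level was 685 ± 26 CPM at 12.5 nM and 807 ± 58 CPM at 25 nM, which did not pass the test, and 1108 ± 63 CPM at 50 nM, which did. Counts do not separate the introduced fusion transcript from the disrupted gene of the line, and the dose acts on the protein, so this level does not check the labels by itself. Gata2, the GATA factor of progenitor cells (chromosome 6, 88193891 to 88207032), fell from 127 ± 9 CPM to 16.4 ± 2.1 CPM, by 2.94 ± 0.12 on the log2 scale (adjusted p = 4.15e-12, edgeR quasi-likelihood, Benjamini-Hochberg). Its fall was first called at 50 nM, at -0.70 ± 0.09.

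**Figure D1:**
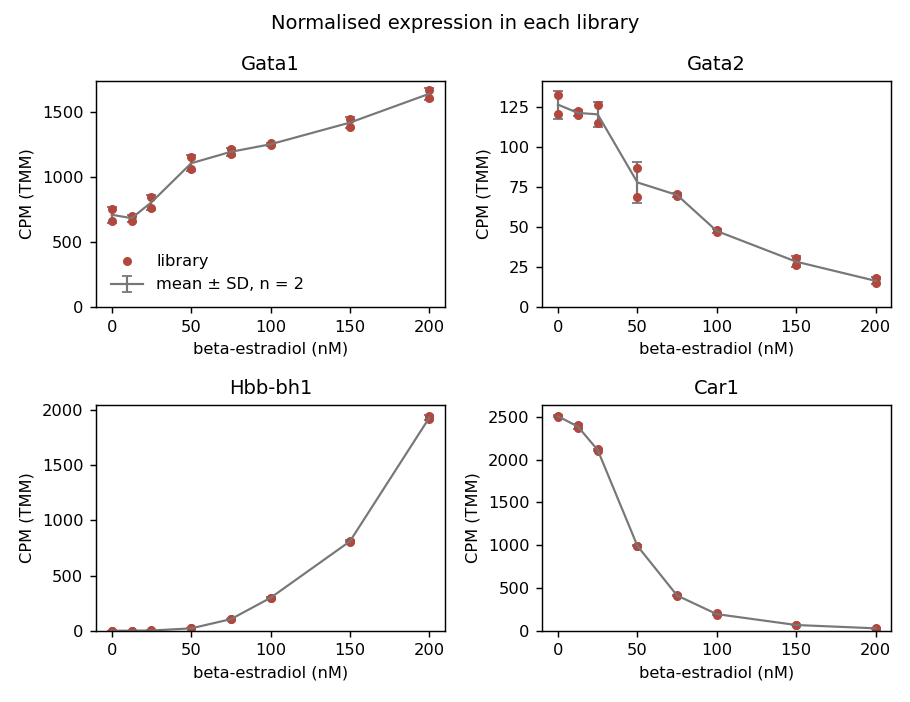
TMM-scaled CPM of Gata1, Gata2, Hbb-bh1 and Car1 against the dose of beta-estradiol in nM, with a point per library, a line through the means and bars for the SD (n = 2). Gata1 rose from 711 to 1643 CPM and Gata2 fell from 127 to 16.4 CPM between 0 and 200 nM, while the embryonic globin Hbb-bh1 reached 1932 CPM and Car1 dropped from 2506 to 28.7 CPM.

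The comparison of 200 nM with 0 nM asked which genes differed at the highest dose given. The counts do not measure nuclear GATA1, and the samples include no cells without the fusion protein. Effects of beta-estradiol itself therefore cannot be told apart from those of GATA1. Embryonic globins led the named genes that rose. Hba-x, the embryonic alpha-type globin (chromosome 11, 32276400 to 32278116), had 0 counts in both 0 nM libraries and 105 ± 0.8 CPM at 200 nM, at least 1130-fold higher when set against 3 counts over the 0 nM group. Hbb-bh1, an embryonic beta-type globin (chromosome 7, 103841637 to 103843164), rose from 0.557 ± 0.253 to 1932 ± 20 CPM, a log2 fold change of 11.73 ± 0.09 (11.33 to 12.27 with each library of the 2 doses left out in turn). Hbb-y, its neighbour (103851749 to 103853216), had 2 counts at 0 nM and 140 ± 1 CPM at 200 nM, a ratio of 2251 with a 95% counting interval from 623 to 18592. The platelet tubulin Tubb1 rose by 10.19 ± 0.19, Tmem184a (chromosome 5, 139802485 to 139819917) by 10.39 ± 0.10, from 0.404 to 553 CPM, and the cartilage matrix gene Matn1 by 8.93 ± 0.13 (8.48 to 9.56 with each library left out in turn, from 0.495 ± 0.254 CPM at 0 nM). Csf2rb2, a beta subunit of the interleukin-3 receptor, rose by 8.36 ± 0.17, the secreted ligand gene Wnt2 by 8.35 ± 0.23 and the water channel gene Aqp8 went from 0.682 ± 0.162 to 178 ± 4 CPM. Acot11, an acyl-CoA thioesterase gene, had 1 count at 0 nM and 54.0 ± 1.8 CPM at 200 nM, a ratio of 1737 (311 to 68647). The ratio was 513 (142 to 4247) for Plac8 with 2 counts at 0 nM and 230 (78.2 to 1119) for Grifin, a galectin-related gene, with 3.

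Il1rl1, the receptor of interleukin-33 (chromosome 1, 40429570 to 40465415), fell furthest among the named genes, from 35.8 ± 0.2 to 0.350 ± 0.104 CPM, a log2 fold change of -6.63 ± 0.23. Car1, a carbonic anhydrase gene (chromosome 3, 14766216 to 14808368), fell from 2506 ± 11 to 28.7 ± 3.1 CPM, by 6.45 ± 0.05 on the log2 scale. The endogenous retroviral gene Erv3 changed by -5.90 ± 0.14, Tmem44 by -5.80 ± 0.25 (-6.43 to -5.34 with each library left out in turn), the surface protein gene Cd109 by -5.65 ± 0.32 and Fam195a by -5.40 ± 0.20. Transport and metal genes were also in this set, with the zinc transporter Slc30a2 at -5.63 ± 0.19, the folate carrier Slc19a1 at -4.53 ± 0.09 and the metallothionein gene Mt2 at -4.51 ± 0.07. Dctd, a deaminase of nucleotide synthesis, changed by -4.94 ± 0.19 (-5.49 to -4.52 with each library left out), Rangrf by -4.36 ± 0.21 and the mitochondrial coactivator gene Ppargc1b by -4.22 ± 0.20. Adjusted p-values of the 24 genes named for this comparison ran from 1.38e-53 for Car1 to 2.50e-18 for Cd109 (edgeR quasi-likelihood, Benjamini-Hochberg). Each differed in the same direction in all 4 pairings of libraries, which the naming rule required.

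In all, 4086 genes were higher and 3977 lower at 200 nM among 10080 tested, with 1986 and 1754 of them changed at least 2-fold. The median fold of the called genes was 1.95 for those higher and 1.87 for those lower. Scaling by library size alone gave 2819 higher and 5396 lower. The median gene moved by -0.36 on the log2 scale with library size and by 0.02 with TMM, and all changes are given relative to the TMM scaling.

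Genes of the red cell's own products rose together at 200 nM. Of the globins and their chaperone 7 of 7 tested members rose, with a median log2 fold change of 6.53, which did not move when the 2 members with 3 or fewer counts at 0 nM were set at their bound (camera adjusted p = 7.36e-05). The adult alpha globin Hba-a2 went from 279 ± 3 to 10393 ± 214 CPM, although Hba-a1 and Hba-a2, and likewise the adult beta globins, share nearly all their sequence and are uncertain as single genes. Heme synthesis had 12 members higher and 2 lower of 14 (median 1.86, camera adjusted p = 3.31e-05). Alas2, the erythroid enzyme of its first step, rose from 32.9 ± 0.1 to 4321 ± 49 CPM, Abcb10 from 126 to 2166 CPM and Alad from 643 to 3477 CPM, while the ubiquitous first-step enzyme Alas1 fell. All 17 genes of the red cell membrane and skeleton rose (median 2.41, camera adjusted p = 4.97e-09). The anion exchanger Slc4a1 went from 83.2 ± 2.6 to 6685 ± 60 CPM and beta-spectrin Sptb from 232 ± 3 to 2138 ± 86 CPM. Iron uptake and storage had 9 higher and 3 lower of 14 (median 0.51, camera adjusted p = 0.0372, adjusted p = 0.096 with an estimated correlation). The transferrin receptor Tfrc and the ferritin light chain Ftl1 each rose by 2.11 ± 0.03, whereas the second transferrin receptor Tfr2 changed by -3.22 ± 0.06. With library size alone iron uptake had 7 higher and 5 lower.

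Regulators moved both ways. Erythroid transcription factors had 12 higher and 2 lower of 14 (median 1.65, camera adjusted p = 0.00093, adjusted p = 0.0813 with an estimated correlation). Foxo3 rose by 2.65 ± 0.06, Nfe2 by 2.30 ± 0.04 and Gfi1b by 1.67 ± 0.04, while Bcl11a and Lmo4 fell. Progenitor transcription factors and receptors had 5 higher and 7 lower of 12, with a median of -0.78, a mean of 0.24 and a test that did not pass (camera adjusted p = 0.514). Myc fell by 2.06 ± 0.04 and the stem cell factor receptor Kit by 1.44 ± 0.04, while Fli1, a megakaryocyte factor, rose by 6.41 ± 0.20 and Sfpi1, which encodes the myeloid factor PU.1, by 3.96 ± 0.12. Erythropoietin receptor signalling had 7 higher and 3 lower of 11 (camera adjusted p = 0.216). Its survival gene Bcl2l1 rose by 4.10 ± 0.04 and Pim1 by 3.18 ± 0.04, and the signal transducer Stat5a fell by 1.79 ± 0.07.

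Genes of organelle and protein clearance rose. Autophagy and organelle clearance had 16 higher and 2 lower of 18 (median 1.69, camera adjusted p = 9.21e-05), with the cargo receptor Sqstm1 at 2.18 ± 0.03, Gabarap at 2.43 ± 0.04 and Bnip3l, a receptor for the removal of mitochondria, at 1.61 ± 0.04. Ubiquitin enzymes of erythroid maturation had 8 higher and 1 lower of 10 (median 1.27, camera adjusted p = 0.000757), with Ube2l6 at 3.64 ± 0.05 and Ube2o at 3.63 ± 0.07. All 10 cyclin-dependent kinase inhibitors and antiproliferative genes tested rose (median 2.49, camera adjusted p = 0.000101). Btg2 went from 14.0 ± 0.4 to 700 ± 15 CPM and Cdkn1a from 112 ± 2 to 586 ± 4 CPM. P53 targets, of which 4 tested members stand in another list too, had 11 higher of 12 (median 1.84, camera adjusted p = 5.76e-05), among them Trp53inp1 at 4.82 ± 0.06 and Mdm2 at 1.83 ± 0.05. Apoptosis regulators had 9 higher and 4 lower of 15 (camera adjusted p = 0.224), with Bax at 1.07 ± 0.04 and Bid at -1.40 ± 0.05.

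Genes of ribosome production fell, and those of DNA replication fell at the top doses. All 30 ribosome biogenesis genes fell at 200 nM, with a median of -1.78 (camera adjusted p = 2.5e-12), among them the nucleolar proteins Npm1, from 2429 ± 3 to 843 ± 4 CPM, and Nolc1, from 618 ± 3 to 122 ± 2 CPM. DNA replication genes had 3 higher and 22 lower of 26 (median -0.67, camera adjusted p = 3.87e-05, adjusted p = 0.0723 with an estimated correlation), with Uhrf1 at -1.40 ± 0.04 and the replicative helicase gene Mcm6 at -0.96 ± 0.03. At 50 nM 13 of them were higher (camera adjusted p = 0.000254, adjusted p = 0.0978 with an estimated correlation), at 100 nM 11 were higher and 6 lower, and at 150 nM 4 were higher and 19 lower (camera adjusted p = 0.0134, adjusted p = 0.226 with an estimated correlation), although scaling by library size alone gave 8 higher and 1 lower at 50 nM, and 7 higher and 13 lower at 100 nM. Mitosis genes had 20 higher and 1 lower of 24 at 50 nM, 22 and 1 at 75 nM, 20 and 1 at 100 nM, and 16 and 6 at 200 nM (median 0.44, camera adjusted p = 0.0271, adjusted p = 0.259 with an estimated correlation). Nusap1, a spindle protein gene, rose by 2.21 ± 0.05 at 200 nM and the proliferation marker Mki67 by 1.18 ± 0.04, and library size alone gave 12 higher and 10 lower mitosis genes at that dose.

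Metabolic lists were mixed. Nuclear-encoded oxidative phosphorylation had 8 higher and 23 lower of 35 at 200 nM (median -0.29, camera adjusted p = 0.0186, adjusted p = 0.409 with an estimated correlation), with Cyc1 at -1.17 ± 0.04 and Cox6a1 at 0.93 ± 0.04. Glycolysis had 6 higher and 11 lower of 19 and did not pass (median -0.51, camera adjusted p = 0.218), with Ldha falling from 2393 ± 54 to 397 ± 15 CPM, Pkm at -2.10 ± 0.04, and Bpgm, the red cell enzyme that makes bisphosphoglycerate, at 2.61 ± 0.07. Its median and mean differed in sign at 75, 100 and 150 nM. Cholesterol synthesis had 14 higher and 2 lower of 19 (median 0.56, camera adjusted p = 0.0105, adjusted p = 0.0708 with an estimated correlation), with Fdft1 at 1.64 ± 0.04 and Dhcr7 at -2.21 ± 0.06, and 10 higher and 6 lower with library size alone. Cytosolic ribosomal proteins had 26 higher and 16 lower of 62 with a median of 0.04 (camera adjusted p = 0.565), a direction that flipped to 2 higher and 52 lower with a median of -0.34 under library size alone. Rpsa was at 1.01 ± 0.03.

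Of the stress and signalling lists at 200 nM, immediate early genes alone passed the test, and that with the preset correlation only. At lower doses the preset correlation also called heat shock genes lower from 75 to 150 nM (camera adjusted p = 0.0338, 0.0428 and 0.0448), integrated stress genes higher at 25 and 50 nM (0.00931 and 0.0382), estrogen receptor targets higher at 25 nM (0.0395) and immediate early genes higher from 25 to 150 nM, the last at 25 nM with an estimated correlation too (0.0371). The integrated stress and unfolded protein response had 8 higher and 8 lower of 16 (camera adjusted p = 0.872), with a median of 0.07 that turned to -0.31 under library size alone. Ppp1r15a was at 3.65 ± 0.05 and the serine synthesis gene Psat1 at -1.80 ± 0.03. Heat shock genes had 2 higher and 6 lower of 9 (camera adjusted p = 0.106), and the mitochondrial chaperone gene Hspd1 was at -2.19 ± 0.03. Immediate early genes had 8 higher and 2 lower of 10 (median 2.64, camera adjusted p = 0.0422, adjusted p = 0.103 with an estimated correlation), with Jun at 5.14 ± 0.21 and Dusp1 at 4.05 ± 0.10. Interferon response genes had 5 higher and 1 lower of 7 (camera adjusted p = 0.234), with Ifi27l1 at 2.36 ± 0.06 and Bst2 at -1.97 ± 0.24. Estrogen receptor targets had 4 higher and 2 lower of 7 (camera adjusted p = 0.309), with Ctsd at 2.20 ± 0.03 and Rara at -3.15 ± 0.29.

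Markers of other blood cells also moved at 200 nM. Megakaryocyte and platelet markers had 5 higher and 1 lower of 7 (median 4.13, camera adjusted p = 0.0437, adjusted p = 0.103 with an estimated correlation), with Itgb3 rising from 7.77 ± 0.64 to 404 ± 11 CPM and Pf4 from 0.373 ± 0.007 to 6.68 ± 0.46 CPM. Granulocyte and macrophage markers had 4 higher of 4 (camera adjusted p = 0.106), of which Csf2rb, a shared cytokine receptor subunit, reached 586 ± 14 CPM and Cd68, Fcgr3 and Cebpb stayed under 2 CPM. Mast cell and basophil markers had 1 higher and 3 lower of 6 (camera adjusted p = 0.58), the higher being Srgn. Lists of lymphocyte, fibroblast and endothelial markers had fewer than 3 members with enough counts and were not tested, and mitochondrially encoded genes were not analysed here. Over the 27 lists tested at 200 nM, 13 were called higher and 3 lower, and 7 and 1 with an estimated correlation. Adjusted over the list alone, the counts were equal in 25 of the 27 lists, with 7 higher and 11 lower glycolysis genes and 5 higher and 2 lower estrogen receptor targets in the others.

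**Figure D2:**
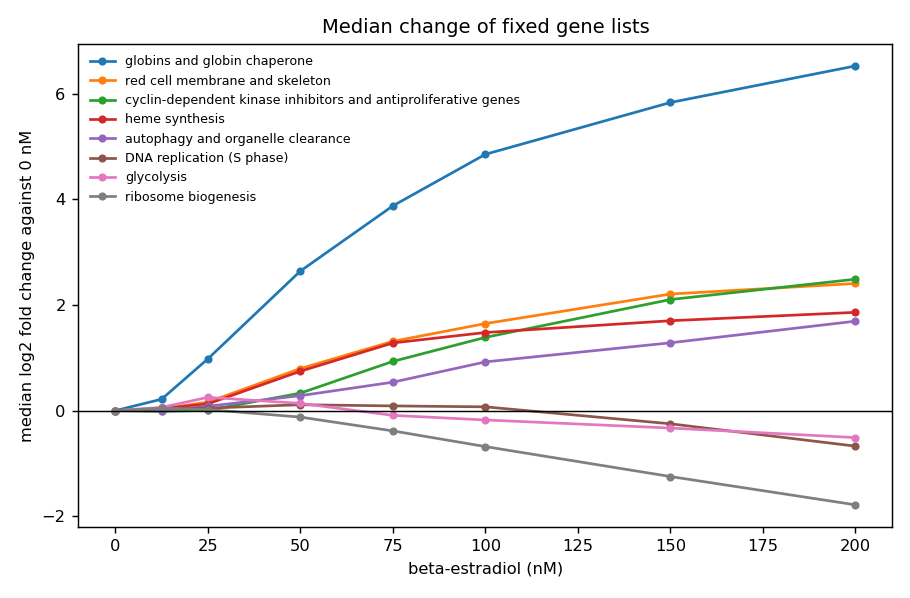
Median log2 fold change against 0 nM (vertical axis, TMM scaling) of the tested members of 8 gene lists at each dose of beta-estradiol in nM (horizontal axis). The globin median reached 6.53 at 200 nM, the ribosome biogenesis median fell to -1.78, and the glycolysis median was 0.25 at 25 nM and -0.51 at 200 nM.

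The lower doses asked at which amount of beta-estradiol expression first moved. At 12.5 nM 28 genes were higher and 23 lower than at 0 nM. The antisense RNA Kcnq1ot1, an imprinted long transcript (chromosome 7, 143203458 to 143296549), fell to 24.3 ± 0.9 CPM, by 1.31 ± 0.08 on the log2 scale, with the limit that reads of the overlapping gene Kcnq1 cannot be separated from it without strand. The chromatin genes Ash1l and Mll2 changed by -0.42 ± 0.10 and -0.39 ± 0.05, and Ddx26b, Ube2l6 and Ano1 by 0.43 ± 0.09, 0.38 ± 0.06 and 0.37 ± 0.09. These counts depended on the tool and the libraries. DESeq2 called 25 higher and 13 lower, and leaving out 0 nM replicate 2 left 8 higher and 9 lower. With the trend of each library with transcript length removed, in a test chosen after the data were seen, 9 of the 21 lower genes with a length were still called lower, and the median change of the 21 went from -0.333 to -0.269. Of the lists 9 passed the test as higher at 12.5 nM with the preset correlation, among them glycolysis (median log2 change 0.06, camera adjusted p = 0.00126), DNA replication (0.04, p = 0.00147), iron uptake and storage (0.05, p = 0.0103) and globins (0.22, p = 0.0109). With an estimated correlation iron uptake alone passed (adjusted p = 0.0498).

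At 25 nM 302 genes were higher and 103 lower. Btg2 rose by 1.11 ± 0.08, the beta globin entry Hbb-b1 by 1.03 ± 0.17 and Mboat2 by 0.98 ± 0.11, while Kcnq1ot1 was at -0.89 ± 0.08, the complement regulator Cd55 at -0.58 ± 0.12 and Rbm26 at -0.52 ± 0.11. Of the glycolysis genes 12 of 19 rose at this dose, 14 when adjusted over the list alone (median 0.25, camera adjusted p = 9.3e-15, adjusted p = 0.0171 with an estimated correlation). Heme synthesis had 7 of 14 higher and globins 5 of 7. The counts came to 174 higher and 225 lower with library size alone, 49 lower with DESeq2, and 150 higher and 39 lower without 0 nM replicate 2.

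From 50 nM upward the response was broad. At 50 nM 1896 genes were higher and 1481 lower (library size alone 1336 and 2330). The named genes that rose were Tmem184a at 5.99 ± 0.18, Hbb-bh1 at 5.28 ± 0.18 and Csf2rb at 3.69 ± 0.11. Cd109 was at -2.16 ± 0.18, the galectin gene Lgals9 at -2.12 ± 0.05 and the sialyltransferase gene St8sia4 at -1.51 ± 0.11. At 75 nM 2928 were higher and 2715 lower (2143 and 3811), with Tubb1 at 7.02 ± 0.29 and Lgals9 at -3.39 ± 0.06. At 100 nM 3436 were higher and 3275 lower (2452 and 4621), with Tmem184a at 8.66 ± 0.12 and Acot11 at a ratio of 835 over 1 count at 0 nM (149 to 33022). At 150 nM 3805 were higher and 3686 lower (2759 and 5083), with Hba-x at least 349-fold higher against 3 counts over the 0 nM group and Car1 at -5.20 ± 0.04. Over all doses 8698 genes had a dose effect in the F test. A rising trend was called for 4002 genes and a falling trend for 3806, or 2830 and 5167 with library size alone.

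**Figure D3:**
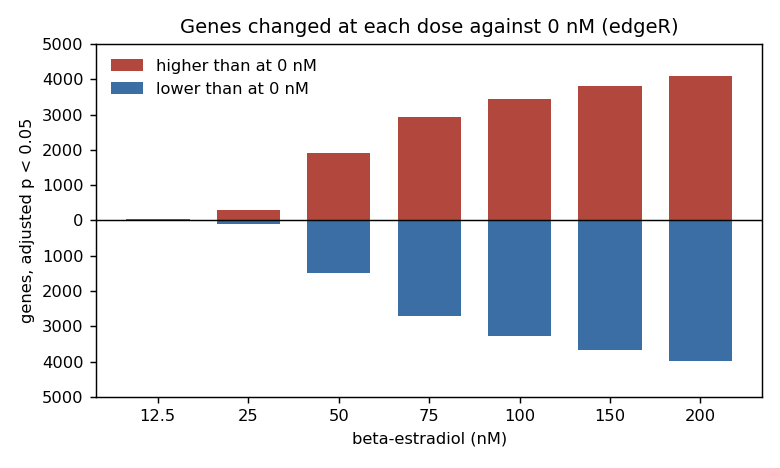
Number of genes higher (bars above 0) and lower (bars below 0) than at 0 nM at each dose of beta-estradiol in nM, by the edgeR quasi-likelihood test with TMM scaling and adjusted p under 0.05. The bars grow from 28 and 23 genes at 12.5 nM to 4086 and 3977 genes at 200 nM.

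Steps between neighbouring doses asked where expression moved and whether it levelled off. Between 12.5 and 25 nM 110 genes changed, among them the mitochondrial death gene Bnip3 at 1.08 ± 0.09, Alas2 at 0.78 ± 0.05 and the acetylcholinesterase gene Ache at 0.74 ± 0.08, with Rfx7, St8sia4 and Pank3 lower. This count was 193 with no filter on low counts and 50 without 12.5 nM replicate 1. Between 25 and 50 nM 2639 genes changed, with Slc4a1 at 2.76 ± 0.03, Tmem184a at 3.15 ± 0.12 and Lgals9 at -1.70 ± 0.05, and with Ces2g and Car1 lower. Between 50 and 75 nM 3260 changed, with Hbb-bh1 at 2.26 ± 0.06 and Fam198b at -0.80 ± 0.11. Rnf187 rose by 1.81 ± 0.40 and the lysosomal membrane gene Lamp1 by 1.76 ± 0.25 at this step, but both varied between the 50 nM libraries, at 92.8 ± 57.7 and 122 ± 34 CPM. From 75 to 100 nM 2773 genes changed, with Matn1 at 1.75 ± 0.09, the platelet and leukocyte gene Plek rising from 23.7 ± 0.7 to 67.2 ± 1.3 CPM and Erv3 at -0.98 ± 0.09.

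The upper steps still moved many genes. From 100 to 150 nM, a step of 50 nM, 4120 genes changed, with Aqp8 at 1.63 ± 0.10, Slc26a11 at 1.49 ± 0.17, Mt2 at -1.55 ± 0.08 and Slc19a1 at -1.45 ± 0.08. From 150 to 200 nM 3966 changed, with Hbb-y at 2.96 ± 0.11, Hba-x at 1.70 ± 0.10, Ypel2 at 1.32 ± 0.17, the cell cycle ubiquitin ligase gene Skp2 at -1.17 ± 0.12 and the transglutaminase gene Tgm2 at -1.16 ± 0.07. Changes of at least 2-fold numbered 3, 228, 218, 107, 214 and 160 over the 6 steps. Set against 200 nM, 8073 genes differed at 12.5 nM, 8047 at 25 nM, 7693 at 50 nM, 7152 at 75 nM and 6458 at 100 nM. Genes changed at least 2-fold at 200 nM had covered a median of 21.3% of that log2 change at 50 nM if higher and 13.6% if lower, 59.2% and 46.3% at 100 nM, and 82.2% and 72.4% at 150 nM, with the 0 nM libraries shared by all of these values.

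Some genes did not follow the dose one way. At an intermediate dose 292 genes peaked and 207 dipped, most of them by little, since peaks of at least 2-fold against both 0 and 200 nM numbered 0, 1, 0, 6, 7 and 0 and dips 0, 0, 3, 13, 5 and 0 from 12.5 to 150 nM. Genes are named here under the naming rule, with its limit of 20 CPM, and are not always the strongest peaks. At 25 nM 29 peaked, and Bnip3 was first under the rule, at 41.8 ± 0.3 CPM against 21.2 ± 0.6 at 0 nM and 13.0 ± 0.5 at 200 nM. Pfkl, a subunit of the glycolytic enzyme phosphofructokinase, stood at 141 ± 3, 207 ± 7 and 47.0 ± 0.8 CPM, and Ero1l, an oxidase of the endoplasmic reticulum, at 111 ± 1, 153 ± 7 and 97.1 ± 2.2 CPM. Pfkl and Ddah2 were also the 2 genes that peaked at 12.5 nM. At 50 nM 131 genes peaked, with Ubac1, Eif5a2 and Usp6nl named under the rule. At 75 nM 183 peaked, with Wbscr16, Nol9 and the proliferation factor Mybl2 named, the last at 36.5 ± 1.1 CPM against 21.8 ± 2.2 and 18.8 ± 1.1. Nol9 varied between the 0 nM libraries and passed narrowly, at 120 ± 3 CPM against 64.0 ± 12.9 at 0 nM and 62.3 ± 0.4 at 200 nM (adjusted p = 0.0432). At 100 nM 170 peaked, with Arhgef10l, Rasl11a and the retinoblastoma family gene Rbl1 named under the rule, and at 150 nM 60, with Arhgef10l, Ahnak and Zbtbd6 named.

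Dips numbered 10, 14, 96, 128, 90 and 20 from 12.5 to 150 nM. Kcnq1ot1 dipped at 12.5, 25 and 150 nM. The nuclear RNA Malat1 dipped at 12.5 nM, to 89.4 ± 7.7 CPM against 115 ± 0.1 at 0 nM and 595 ± 4 at 200 nM, as did Mll2. Actr3b and the utrophin gene Utrn dipped at 25 nM. Cd55 fell to 15.8 ± 0.2 CPM at 50 nM, against 36.8 ± 1.6 at 0 nM and 35.0 ± 2.3 at 200 nM, and the amino acid transporter gene Slc7a8 to 81.0 ± 4.9 CPM, against 163 ± 6 and 208 ± 10, while Plxnc1 dipped at the same dose. Ces2g led the named dips at 75 and 100 nM, Slc26a2 dipped at 100 and 150 nM and Mfsd2b at 150 nM. Leaving out 0 nM replicate 1 or 2 reduced the dips to 125 or 128.

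The half-maximal dose asked where groups of genes reached the midpoint of their change at 200 nM. Expression had not levelled off there, with 3966 genes changed from 150 to 200 nM, so it is not the midpoint of a full response. The length of the exposure is not given, so the amount needed cannot be told from the speed of response. On the log2 CPM scale the 1986 genes higher at 200 nM had a median of 84.9 nM (83.3 to 85.3 over all series that take 1 of the 2 libraries at each dose) and the 1754 genes lower had 105.6 nM (104.0 to 106.0). Genes lower lay 20.7 nM above genes higher (19.6 to 22.7), with the same sign in every such series. The order was reversed on linear CPM, where genes higher had 114.2 nM and genes lower 82.9 nM, so it depended on the scale. Among the lists on log2 CPM, globins had a median of 58.3 nM (56.9 to 61.2), heme synthesis 58.7 nM (56.7 to 62.5), the red cell membrane and skeleton 66.7 nM (65.7 to 67.7) and erythroid transcription factors 69.9 nM (61.2 to 71.1). P53 targets stood at 105.8 nM (100.4 to 113.4), ribosome biogenesis genes that fell at 116.5 nM (115.0 to 118.3) and DNA replication genes that fell at 152.7 nM (148.4 to 155.3). The last value rests on 8 genes, those of the list at least 2-fold lower at 200 nM, and does not describe the whole list. Linear CPM gave the lists another order, with globins at 131.4 nM, heme synthesis at 88.7 nM, the red cell membrane and skeleton at 101.8 nM, erythroid transcription factors at 91.9 nM, p53 targets at 133.3 nM, ribosome biogenesis genes at 91.4 nM and DNA replication genes at 139.0 nM.

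**Figure D4:**
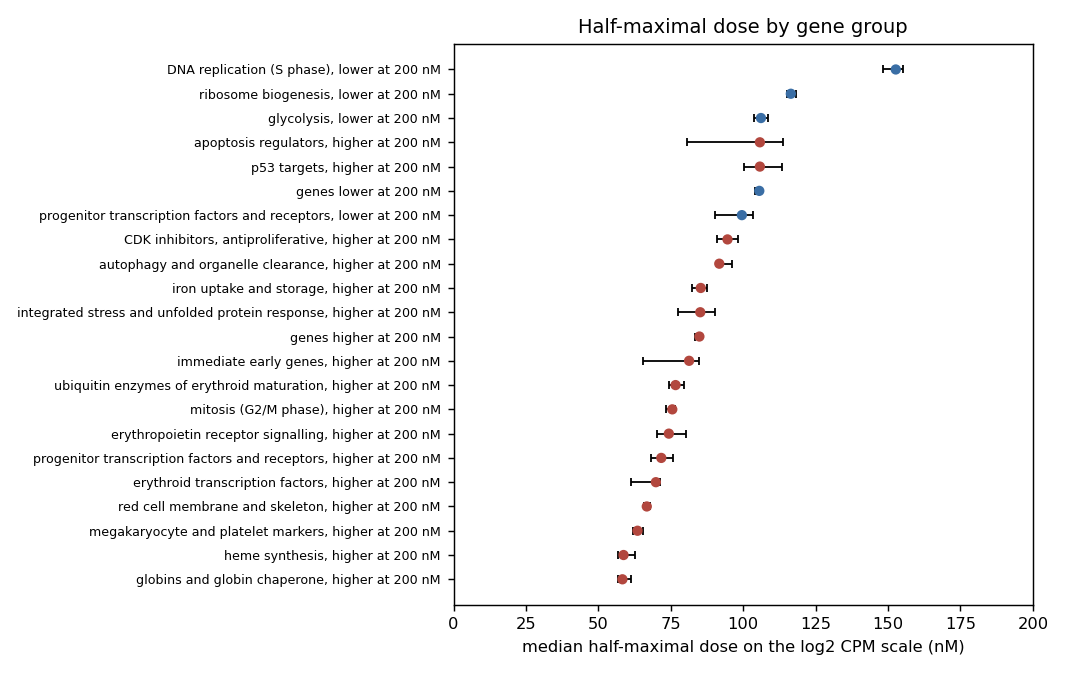
Median half-maximal dose of beta-estradiol in nM (horizontal axis, log2 CPM scale) of all genes changed at least 2-fold at 200 nM and of lists with at least 5 such genes, red for genes higher and blue for genes lower, with bars from the lowest to the highest value over all series of 1 library per dose. The half-maximal dose is the midpoint of the change at 200 nM, where expression had not levelled off. On this scale globins at 58.3 nM and heme synthesis at 58.7 nM lie lowest and falling DNA replication genes at 152.7 nM highest, whereas on linear CPM, not drawn, falling progenitor genes at 67.9 nM lie lowest and apoptosis regulators at 142.9 nM highest.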

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

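The alternatives with matched genes, without the 200 genes that varied together and with percentiles of lists were chosen after the data were seen, and all others before. For named genes at 200 nM the alternatives were DESeq2 size factors, DESeq2, a replicate block and each library at 0 and 200 nM left out. All 147 kept the call and direction, as a choice of the strongest changes made likely. List tests had an estimated correlation in place of DESeq2, and 181 of 189 kept both, the other 8 being lost with that correlation. Neither total includes library size, the filters or limma-voom. With library size 7036 of the 8063 genes called at 200 nM were called again, 6796 in the same direction. Of the counts, 678 of 722 alternatives stayed within 1.5 times, and of the half-maximal doses 427 of 521 within 1 SD. The last total includes each library left out in turn, and the same libraries gave the SD, so it says little about changes of method. Every other reading moved the median of genes higher by more than 1 SD, and all but no smoothing moved that of genes lower. Depth limits the fold changes of genes with 3 or fewer counts at 0 nM, which are given as bounds or with counting intervals.

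A 2-fold minimum left 2 genes higher and 3 lower at 12.5 nM, 20 and 5 at 25 nM, 231 and 133 at 50 nM, 761 and 324 at 75 nM, 1104 and 624 at 100 nM, 1595 and 1168 at 150 nM, and 1986 and 1754 at 200 nM, by its construction. At 12.5 nM limma-voom gave 18 higher and 12 lower, DESeq2 13 lower, and the 4 libraries alone 47 lower. At 25 nM DESeq2 gave 49 lower and library size alone 174 higher and 225 lower, and at 50 nM library size alone gave 2330 lower. With no filter on low counts 14648 genes were tested and 193 changed from 12.5 to 25 nM. Camera with an estimated correlation called 7 lists higher and 1 lower at 200 nM. Apart from the 2-fold minimum and library size, the cause was not tested.

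Leaving out each library in turn gave 8 to 36 genes higher and 9 to 25 lower at 12.5 nM, 150 to 369 higher and 39 to 117 lower at 25 nM, 50 to 146 changed from 12.5 to 25 nM, and 125 to 211 dips. A lone library left at a dose was assumed to vary like the others. Without 0 nM replicate 1 or 2 the 12.5 nM counts were 16 and 10 or 8 and 9, and the 25 nM counts 182 and 44 or 150 and 39. Without 12.5 nM replicate 1 or 2 the 12.5 nM counts were 18 and 11 or 10 and 9. Without 25 nM replicate 2 the 25 nM counts were 194 and 39 and the step from 12.5 nM 65 genes, and without 25 nM replicate 1 the count lower was 67.

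The median half-maximal dose of genes higher and lower was 77.6 and 100.8 nM with a 4-fold minimum (difference 23.2), 85.8 and 104.9 nM with DESeq2 size factors (19.0), 70.6 and 84.8 nM with the mean of 100, 150 and 200 nM as the end point (14.2), 87.1 and 105.0 nM with matched genes (18.0), 83.5 and 106.2 nM with a prior count of 0.5 (22.7), and 84.1 and 104.7 nM with interpolation in log2 dose. It was 85.6 nM for genes higher with no smoothing. Linear CPM reversed the order, at 114.2 and 82.9 nM (-31.3), which follows from reading the midpoint on another scale. Without each library in turn the medians were 84.4 to 85.1 nM and 105.1 to 106.1 nM.

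Replicate numbers paired the libraries weakly if at all. Deviations of same-numbered libraries correlated between -0.0583 and 0.0960 over 28 pairs of doses, and 12 of 16 libraries correlated best with their own number. The libraries of a dose deviate from their mean by equal and opposite amounts, so both always gave the same answer in that count. A replicate block gave 4082 higher and 3966 lower at 200 nM and 27 and 21 at 12.5 nM, and moved no count by more than 1.5 times.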

Other observations

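The tests in this part, including the percentiles of lists, were chosen after the results they bear on were seen. Rn45s, the precursor of ribosomal RNA, was singled out after its values were seen. It rose from 87073 ± 626 CPM at 0 nM to 177226 ± 6606 CPM at 200 nM (SD, n = 2), a log2 fold change of 1.03 ± 0.04 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.2e-09). Without TMM scaling the rise was smaller, from 9.57% to 15.0% of all counts. These counts do not tell the precursor from the ribosomal RNA made from it, so they do not measure its synthesis. Lars2, the mitochondrial leucyl-tRNA synthetase gene, was also picked after its values were seen and rose from 2010 ± 41 to 4550 ± 340 CPM. The cause of either rise, including how reads were assigned, was not tested.

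List medians of the half-maximal dose were set against 10000 random lists matched on direction and size of change. Heme synthesis lay at the 0.01 percentile on log2 CPM and at 0.96 on linear CPM, and falling DNA replication genes at 99.98 and 99.99. Ribosome biogenesis genes lay at 97.3 and 97.1, p53 targets at 99.3 and 98.7, and erythroid transcription factors at 4.85 and 3.80. Globins lay at 4.83 on log2 CPM and at 68.4 on linear CPM, and red cell membrane genes at 1.78 and 5.38. Of these lists the globins alone changed side of the middle between the scales. Among the other lists iron uptake and storage (61.5 and 30.1), falling glycolysis genes (51.2 and 30.8), immediate early genes (64.9 and 47.8) and megakaryocyte markers (13.0 and 53.7) did so too. Percentiles were not adjusted for the number of lists.

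Glycolysis genes were higher at 25 nM, with a median log2 change of 0.25, against 0.06 at 12.5 nM, 0.14 at 50 nM and -0.09 at 75 nM, and the list also passed at 12.5 nM, with the preset correlation only (camera adjusted p = 0.00126). The median was 0.203 once trends with GC content and transcript length were removed, which argues against bias along those traits as the whole cause. Bias tied to base composition at the transcript start was not tested for this list and stays open. A low-oxygen type response is a candidate explanation that stays open. Among 22 other low-oxygen genes 4 rose at 25 nM, namely Pdk1, Kdm3a, Higd1a and Selenbp1, whose place in the list is uncertain, and the list's median of 0.08 lay at the 99.36 percentile of random lists matched on expression, yet its median was higher still at 75 nM, at 0.21. The dose and the culture conditions of the 25 nM samples stay open too, as untested.

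Genes lower at 12.5 nM had long transcripts, with a median of 11644 bases for the 21 with a length against 3299 for all genes tested. Across genes the change at 12.5 nM correlated with transcript length at a Spearman rho of -0.0946, genes not being independent replicates, and 2 replicate pairs differed along length by more, up to 0.111 at 25 nM. With each library's length trend removed, 9 of the 21 were still called lower and their median change went from -0.33 to -0.27 with median standard errors of 0.0598 and 0.0595. The change became smaller and its error did not, and what ended each call was not tested further. Their median was -0.255 at 25 nM, against -0.36 at 12.5 nM over all 23 genes, which lies between what 0 nM libraries standing apart and a change at 12.5 nM alone would give. At 50 nM the median was -0.145, and it was positive at 75, 100, 150 and 200 nM, at 0.091, 0.082, 0.070 and 0.348. The response to dose was broad at these doses and enters those values. Length bias, the 0 nM libraries and the dose may each contribute and cannot be told apart here.

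A set of genes varied together between replicates, with Rnf187 and Lamp1 among the strongest, and the leading axis held 24.1% of the replicate variance over 5079 genes. Of the genes named in the report, Rnf187, Lamp1, Aqp8, Nol9, Rbl1 and Gata2 were among the 200 strongest. These 200 had a median GC of 70.5% in the first 200 bases, above all 10000 sets matched on expression (percentile 100, median 62.3%), which is consistent with base composition at the transcript start acting during library construction, although genes were not matched on other traits. A second set of 200 genes, chosen without the 50 and 75 nM libraries, shared 120 genes with the first. Its mean level, with genes of negative sign on the axis counted in reverse, stepped up by 0.383 (log2) from 50 to 75 nM. The 50 nM libraries differed by 0.440 of that step, between the limits set for and against dose alone. A difference between libraries up to 50 nM and from 75 nM upward and an effect of dose cannot be told apart here. Without the first set of 200 genes, the number of genes changed from 50 to 75 nM was 3126.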
